A study of Homo sapiens with 6 samples.

How the data were processed

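Gene expression was measured on 6 Affymetrix Human Gene 1.0 ST arrays, 1 per sample. The samples were air-liquid interface cultures of primary human airway epithelium. In such cultures cells grow on a porous support with air above and medium below, and form an epithelium of ciliated, secretory and basal cells. The series design names 3 donors without known disease, whose cultures received IL-13 at 20 ng/mL on both faces or vehicle for 21 days, and the labels number 3 biological replicates in each group. Groups and replicate numbers were taken from the labels.

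The deposited table held 1 value for each of 30441 transcript clusters on each array, already on a log2 scale, with values from 1.18 to 13.05. The tools named for it are Partek and RMA, per the submitters' processing notes. RMA corrects the background, sets the arrays to a common distribution and summarises the probes of a cluster. The options and versions of both tools are not given in the sources used here. Array medians lay between 5.52 and 5.61, and the deposited log2 values were used without further scaling. The arrays did not share a common spread. The lower and upper quartiles were 4.41 and 6.89 for IL-13 replicate 2, against 4.20 and 7.02 for IL-13 replicate 3. Quantile normalization of the deposited values was an alternative. Scanner files were not used here, so background, probe summary and scan date could not be varied, and no detection call was made. A low level is therefore given below as a percentile of all genes tested, and a fold change from such a level is open to compression by background signal. The number of arrays limits the precision of every value.

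Of the clusters, 18983 named 1 gene in the platform annotation, 1709 named several and 9749 named none. Those naming 1 gene covered 17987 genes, of which 17960 were matched by gene identifier to a RefSeq gene table of GRCh38.p14, used for current symbols, and 27 kept the symbol of the annotation. Where several clusters named a gene alone (732 genes), the cluster with the highest mean over the 6 arrays stood for it. No filter on level was applied. Clusters naming several genes or none entered only 1 of the alternatives. The genome build of the array design is not given in the sources used here, so no coordinates are given.

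IL-13 and vehicle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, two-sided), and p-values were adjusted over all 17987 genes by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are differences of mean log2 values, IL-13 minus vehicle. Errors are the SD over 3 arrays for a group mean and the limma standard error (SE) for a difference. Shifts of 26 gene lists were tested with camera, a limma test that compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. Its p-values were adjusted over the 26 lists. A correlation estimated for each list and fry, a limma test of the list's own genes, were alternatives. For each list, members past the threshold were also counted after Benjamini-Hochberg adjustment over the list alone. The lists held 511 distinct genes, of which 459 were measured. They covered the cell types of the airway epithelium, other cell types a primary culture can carry over, and pathways tied to IL-13, mucus, ion transport, defence, stress and growth.

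Except where stated below, the lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold whose 3 IL-13 values all lay beyond all 3 vehicle values. It also named 22 genes whatever their result, and the 4 members of each list with the smallest p. Of the 22 genes, 18 were measured by a cluster naming 1 gene, and the others are not analysed here. The rule left out of naming genes known only by a placeholder name, in which it counted small nucleolar RNAs, microRNAs, Y RNAs and immunoglobulin segments, and genes that could reveal the sex of a donor.

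Same-numbered samples were checked for pairing. The design gives 3 donors and both treatments, but the labels do not say that a number marks a donor. Deviations from the group means, correlated across the genes tested, gave r = 0.35, 0.10 and 0.31 for replicates 1, 2 and 3, against at most 0.04 for any other pair of an IL-13 and a vehicle sample, and all 6 samples matched their own number best. Every pair exceeded 0.1, the limit set for treating numbers as pairs, replicate 2 by a small margin. Over all 30441 clusters the values were 0.21, −0.03 and 0.16, and 4 of 6 samples matched their own number best. The numbers were used as pairs for the block and for differences within pairs. The main comparison was fitted without a block, as fixed in advance, so variation shared by same-numbered samples stays in its SE. Values with the replicate number as a block are given where they change the call of a list, list member or named gene.

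Alternatives were the replicate block, quantile normalization or median centring of the deposited values, removal of the 40% of genes with the lowest mean, a floor at the 20th percentile of each array, averaging the clusters of a gene, testing every cluster, an intensity trend with a robust prior, array weights, a minimum 2-fold change, and leaving out each array in turn. The block was also combined with an estimated correlation and with leaving out both arrays of a replicate number, choices made after the data were seen. The fit and the list test were tested on simulated data for 17987 genes with the group sizes of this comparison. Of 200 changed genes per set in 10 sets, 19.8% were recovered at a log2 change of 0.5, 71.4% at 1, 96% at 2 and 99.4% at 4, and 3.69% of calls were false. A list shifted by −0.3 was called in 10 of 10 sets, and sets without any change gave 0 gene calls. The simulated genes were drawn independently from normal distributions with the SD estimated for each gene. They had no correlation between genes and no effects shared by a replicate number. In the real data the list that was shifted, ciliated cell axoneme, had an estimated correlation of 0.453. The simulation therefore cannot show how often changed genes were recovered, or how often genes or lists were falsely called, in these data. Plots were drawn with matplotlib 3.10.9.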

Results

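The data were 6 whole-transcript arrays of human airway epithelial cultures, 3 treated with IL-13 at 20 ng/mL for 21 days and 3 treated with vehicle. IL-13 is a type 2 cytokine that signals through the IL-4 receptor alpha chain and the transcription factor STAT6. Each array gave 30441 log2 values with a median between 5.52 and 5.61. Correlations across genes, which are not independent replicates, ran from 0.978 to 0.990 between arrays of a group and from 0.972 to 0.984 between arrays of different groups. No arrays were identical. The first principal component held 38.0% of the variance and separated the groups, with vehicle arrays between −19.1 and −14.5 and IL-13 arrays between 9.63 and 27.5. The second, with 28.5%, set the replicate 3 arrays of both groups (−14.3 and −28.2) apart from the other arrays (5.91 to 14.3).

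The comparison of IL-13 with vehicle addressed how the transcriptome of airway epithelial cultures differed after prolonged IL-13 exposure. After IL-13 a small set of genes rose by a wide margin. CST1, a secreted cysteine protease inhibitor, rose 239-fold from a log2 mean of 4.55 ± 0.45 to 12.44 ± 0.25 (SD, n = 3 each), among the highest values on the arrays. POSTN, the matricellular protein periostin, rose 114-fold from 3.31 ± 0.22, at percentile 4.6 of all genes, to 10.14 ± 0.33. The eosinophil chemoattractant CCL26 rose 20.6-fold, and the inducible nitric oxide synthase NOS2 rose 11.6-fold. The largest decreases were in the glutathione S-transferase GSTA2, the mucosal scavenger receptor DMBT1 and CDC20B, a gene of multiciliated cells, and ran from 4.45-fold to 8.0-fold.

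At an adjusted p under 0.05 in limma, 69 genes were higher and 17 lower after IL-13, of 17987 tested, and 49 and 8 of them changed at least 2-fold. In all 86 genes the 3 IL-13 values lay beyond the 3 vehicle values. Over all genes tested 3303, or 18.4%, had such groups, against 10% by chance. An unadjusted p under 0.05 was reached by 1133 genes in the higher and 1054 in the lower direction. With the replicate number as a block, 113 genes were higher and 59 lower, and these included all 86. Leaving out 1 array gave 21 to 47 higher and 1 to 16 lower genes, the fewest without vehicle replicate 1 (21 and 1), and 18 of the 86 calls were kept whichever array was left out, of which 17 were increases.

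**Figure D1:**
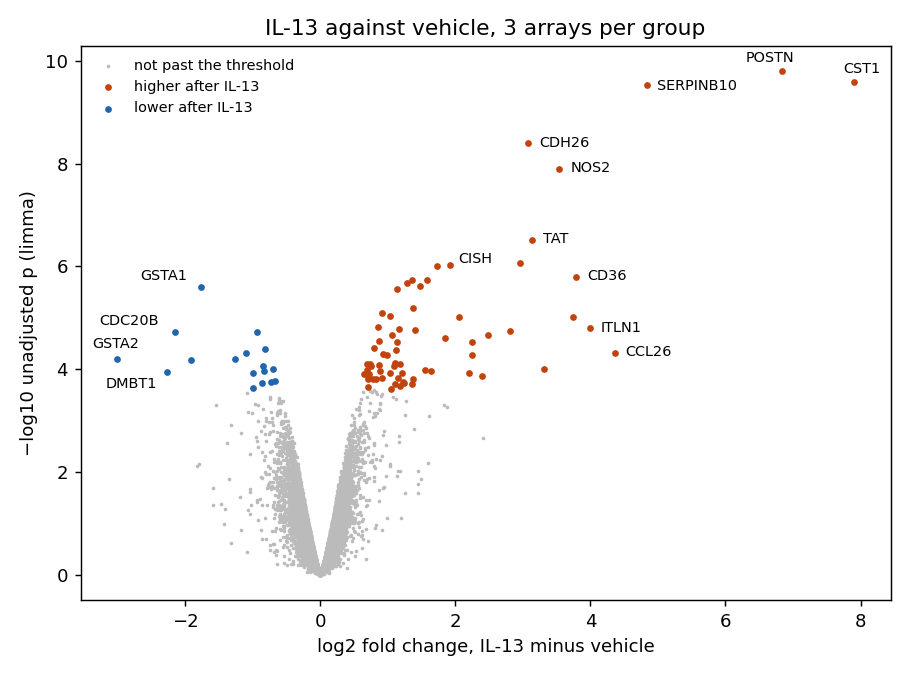
Log2 fold change of each gene (IL-13 minus vehicle, horizontal axis) against −log10 of its unadjusted limma p (vertical axis), 3 arrays per group. Coloured points are the 69 genes higher and 17 genes lower at an adjusted p under 0.05; CST1 at 7.90 and POSTN at 6.83 lie farthest to the right, and GSTA2 at −3.0 lies farthest to the left.

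The 12 largest increases were in CST1, POSTN, SERPINB10, CCL26, ITLN1, CD36, FETUB, NOS2, CEACAM5, TAT, CDH26 and CST2. CST1 (transcript cluster 8065412) had a log2 fold change of 7.90 (SE 0.22, adjusted p = 1.78e-06), and POSTN (transcript cluster 7971077) had 6.83 (SE 0.18, adjusted p = 1.78e-06). SERPINB10, an intracellular serpin, rose by 4.83 (SE 0.14, adjusted p = 1.78e-06), and its 3 IL-13 values had an SD of 0.01. CCL26 rose by 4.36 with a wider error (SE 0.57, adjusted p = 0.0222). ITLN1, the mucus-associated lectin intelectin-1, rose 15.9-fold, from 6.37 ± 0.98 to 10.36 ± 0.48. CD36, a fatty acid and lipoprotein receptor, rose 13.8-fold from percentile 1.2 of all genes to percentile 69.6. FETUB, a secreted protease inhibitor of the cystatin superfamily, rose 13.4-fold, and the cell adhesion molecule CEACAM5 rose 9.95-fold. TAT, tyrosine aminotransferase, rose 8.81-fold, the cadherin CDH26 8.47-fold and the cystatin CST2 7.77-fold. CST1, POSTN, SERPINB10, CD36, NOS2, TAT, CDH26 and CST2 passed the threshold whichever array was left out. FETUB passed in 5 of these 6 fits, ITLN1 in 4, CCL26 in 2 and CEACAM5 in 2. CST1 and CST2 are close relatives in sequence, and how far their probes distinguish them was not tested.

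Small nucleolar RNAs aside, the 12 largest decreases were in GSTA2, DMBT1, CDC20B, CAPN13, GSTA1, GJB7, ABCC4, IFITM10, PLAAT2, RRAD, NR4A2 and GSTA4. GSTA2 fell 8.0-fold (log2 fold change −3.0, SE 0.40, adjusted p = 0.0258) and GSTA1 fell 3.38-fold (−1.76, SE 0.16, adjusted p = 0.00307). GSTA4 fell 1.78-fold. These genes encode alpha-class glutathione S-transferases, which conjugate electrophiles, and sequence similarity among them leaves open how far their probes distinguish them. DMBT1, a scavenger receptor cysteine-rich protein of mucosal secretions, fell 4.81-fold from 8.60 ± 0.49 to 6.34 ± 0.63. CDC20B, whose locus carries microRNAs of multiciliated cells, fell 4.45-fold. The calpain CAPN13 fell 3.78-fold, the connexin GJB7 2.39-fold and ABCC4, an exporter of organic anions and cyclic nucleotides, 2.14-fold. GSTA1 passed the threshold whichever array was left out. CDC20B passed in 3 of these 6 fits, RRAD in 2, and each of the others in 1 or 0. The small nucleolar RNA SNORD116-15, of a kind left out by the naming rule and named after its value was seen, fell by 0.86 on the log2 scale (SE 0.13, adjusted p = 0.0424), more than NR4A2 (−0.85) and GSTA4 (−0.83), and passed in 1 of these fits.

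**Figure D2:**
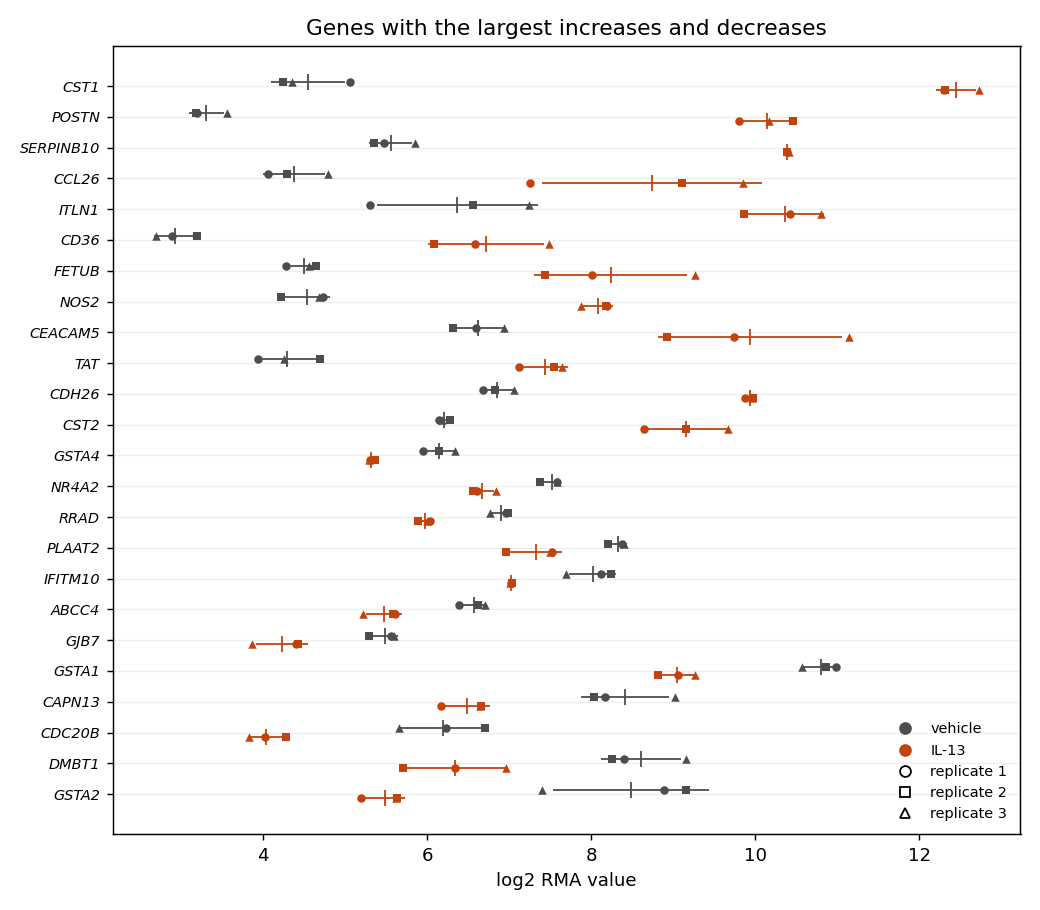
Log2 value on each array for the 12 genes with the largest increase (top) and the 12 with the largest decrease (bottom), small nucleolar RNAs left out. Symbols mark replicate numbers, ticks mark group means and bars mark the SD of 3 arrays. CST1 moved from 4.55 to 12.44 and GSTA2 from 8.48 to 5.48, and in each of these genes the groups did not overlap.

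The IL-13 and type 2 airway signature had a median log2 fold change of 2.08 over 20 measured genes (camera adjusted p = 7.80e-26; adjusted p = 0.0763 with an estimated correlation). Of these genes 10 rose and 0 fell over all genes tested, and 16 rose and 0 fell when adjusted over the list alone. The list was chosen as known responders to IL-13 in airway epithelium. Besides the leading genes it held ALOX15, a lipoxygenase that oxygenates arachidonic acid, which rose 4.74-fold from 9.82 ± 0.64 to 12.07 ± 0.06. CISH, a STAT-induced feedback inhibitor of cytokine signalling, rose 3.77-fold (log2 fold change 1.92, SE 0.15). Of the 6 fits that left out an array, CISH passed in 6 and ALOX15 in 3. CLCA1 had a log2 fold change of 1.17 (SE 0.26, adjusted p = 0.157), from percentile 5.7 of all genes in vehicle.

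In the IL-4 and IL-13 receptor and JAK-STAT list CISH was the 1 gene of 19 that rose, over all genes tested and adjusted over the list alone, and 0 fell. The list as a whole did not shift (camera adjusted p = 0.838); its median was −0.02, the direction of the test, and its mean 0.09. STAT6 differed by 0.04 (SE 0.13), the receptor chain IL13RA1 by −0.31 (SE 0.17) and the decoy receptor IL13RA2, among the lowest values of all genes in vehicle, by 0.49 (SE 0.27). Their adjusted p-values were 0.930, 0.506 and 0.497.

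Goblet and mucous genes had a median of 0.57 over 16 genes (camera adjusted p = 2.72e-07; adjusted p = 0.559 with an estimated correlation). Of these, 2 rose over all genes tested, ITLN1 and the mucus protein FCGBP, and 0 fell; adjusted over the list alone, 10 rose and 1 fell. FCGBP rose 5.62-fold, from 4.52 ± 0.08 to 7.01 ± 0.68, and passed in 3 of the 6 fits that left out an array. The goblet cell transcription factor SPDEF had a log2 fold change of 1.61 (adjusted p = 0.102), CREB3L1 had 1.27 (adjusted p = 0.0708), TFF3 had 0.88 (adjusted p = 0.0739) and FOXA3 had 0.56 (adjusted p = 0.307). With the replicate block 6 members rose, among them SPDEF (adjusted p = 0.0187), CREB3L1 (adjusted p = 0.0332) and TFF3 (adjusted p = 0.0138). GCNT3, a branching enzyme named after its value was seen, had 1.13 (adjusted p = 0.288; with the replicate block 0.00364). The secreted mucin MUC5B differed by −0.55 (SE 0.47, adjusted p = 0.671; with the replicate block SE 0.11 and adjusted p = 0.0815). MUC5B levels varied between cultures (vehicle SD 0.81), and the 3 numbered pairs differed by −0.60, −0.50 and −0.55, a difference that did not pass the threshold in either fit. The O-glycosylation list, which includes enzymes that build mucin glycans, had a median of 0.29 over 24 genes (camera adjusted p = 0.00222, and 0.626 with an estimated correlation). Its medians in numbered pairs 1, 2 and 3 were 0.25, −0.02 and 0.47. GCNT4, a branching enzyme, rose 2.99-fold (log2 fold change 1.58, SE 0.13, adjusted p = 0.0028) and passed in all 6 of those fits. It was the 1 member that rose over all genes tested, 0 fell, and 2 rose and 0 fell adjusted over the list alone. With the replicate block 3 rose, GCNT4, GCNT3 and the sulfotransferase CHST4, which was named after its value was seen and had 0.80 (adjusted p = 0.307; with the replicate block 0.0257). The O-glycosylation shift missed the threshold without IL-13 replicate 3 (camera adjusted p = 0.0925).

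Ciliated cell genes lay below vehicle by small amounts. Of 31 axoneme genes, which encode the motor and scaffold of motile cilia, 29 had a negative log2 fold change, with a median of −0.28 (camera adjusted p = 1.54e-11; adjusted p = 0.626 with an estimated correlation). In limma 0 rose and 0 fell over all genes tested, with or without the replicate block, against 0 and 16 at an unadjusted p under 0.05, and 0 rose and 3 fell adjusted over the list alone. DNAI1, an outer arm dynein chain, had −0.49 (SE 0.12, adjusted p = 0.183), CFAP43 had −0.47 and TPPP3 had −0.39. Regulators of multiciliogenesis had a median of −0.48 over 14 genes (camera adjusted p = 2.13e-07; adjusted p = 0.156 with an estimated correlation). Of these, CDC20B and DEUP1 fell over all genes tested, 0 rose, and 8 fell and 0 rose adjusted over the list alone. DEUP1, a component of the deuterosome on which centrioles multiply, fell 1.76-fold. Of the 6 fits that left out an array, CDC20B passed in 3 and DEUP1 in 2. PLK4, the kinase that starts centriole duplication, had −0.97 (adjusted p = 0.0765; with the replicate block 0.0307), and the ciliated cell transcription factor FOXJ1 had −0.48 (SE 0.12, adjusted p = 0.186). The regulators' shift missed the threshold when the 40% of genes with the lowest mean were removed (camera adjusted p = 0.0599). That step took CDC20B and DEUP1 themselves out of the list. Their log2 means in vehicle and after IL-13 were 6.19 and 4.04 for CDC20B, and 5.58 and 4.76 for DEUP1. The lost call therefore says little about the shift of the full list.

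Club and secretory cell genes had a median of −0.26 over 18 genes (camera adjusted p = 0.00656; adjusted p = 0.626 with an estimated correlation). In limma 0 rose or fell over all genes tested, 2 rose and 3 fell adjusted over the list alone, and 2 and 6 were higher and lower at an unadjusted p under 0.05. With the replicate block 1 rose and 3 fell. SCGB1A1, the club cell secretory protein, was 12.21 ± 0.30 in vehicle and 10.42 ± 1.2 after IL-13, a log2 fold change of −1.79 (SE 0.50, adjusted p = 0.250; with the replicate block 0.0334). The copper protein ceruloplasmin, CP, had −1.38 (adjusted p = 0.177; with the replicate block 0.00361), and TCN1, a cobalamin binder, had 0.91 (adjusted p = 0.219; with the replicate block 0.0186). CYP2F1, a cytochrome P450 named after its value was seen, had −1.58 (adjusted p = 0.329; with the replicate block 0.0167). The list's shift missed the threshold without IL-13 replicate 1 (camera adjusted p = 0.0857).

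**Figure D3:**
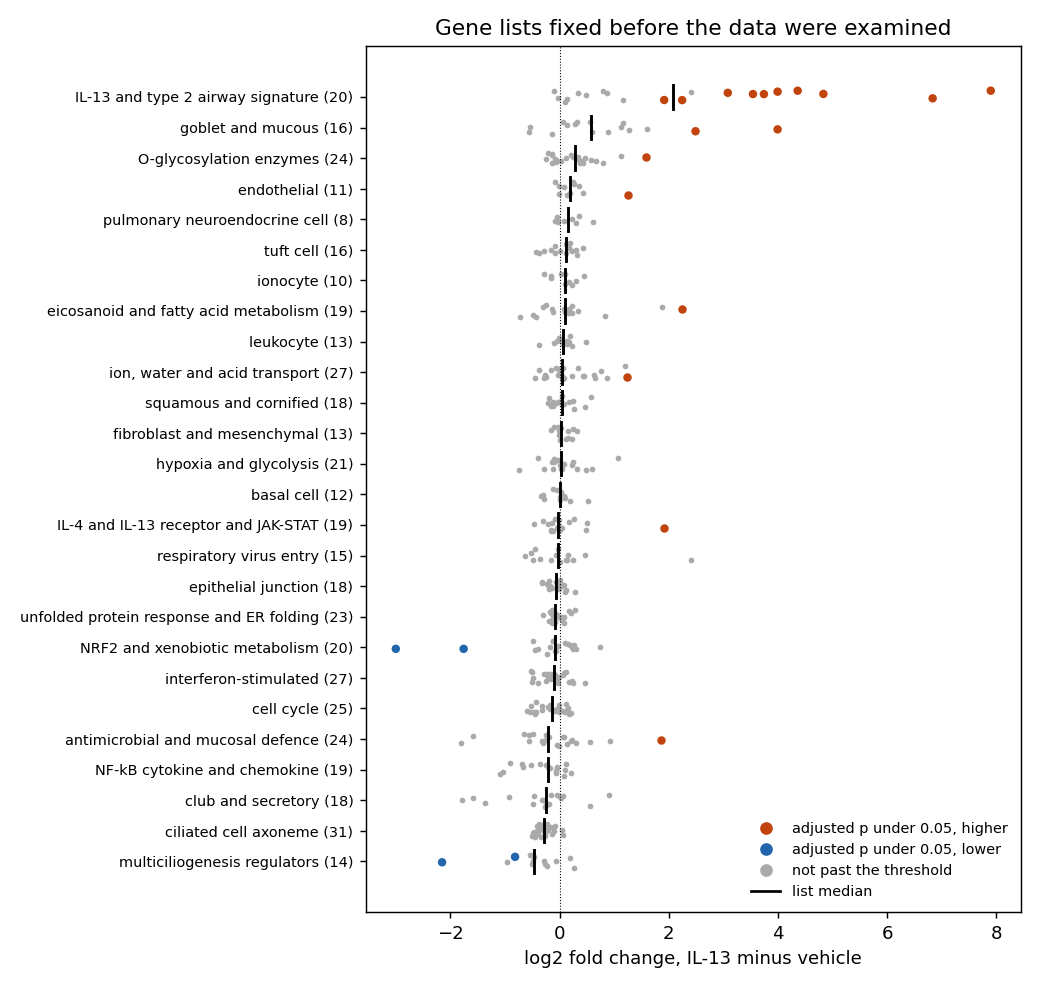
Log2 fold change (IL-13 minus vehicle) of each measured member of the 26 gene lists, with the number of genes in brackets and a black bar at the list median. Coloured points passed an adjusted p under 0.05 over all genes. The type 2 signature has the highest median, 2.08, and the multiciliogenesis regulators the lowest, −0.48.

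Ion, water and acid transport genes showed 1 increase among 27 members, SLC12A2, the basolateral cotransporter that loads epithelial cells with chloride, and 0 decreases. The counts adjusted over the list alone were the same. SLC12A2 rose 2.35-fold (log2 fold change 1.23, SE 0.19, adjusted p = 0.0404) and passed in 2 of the 6 fits that left out an array. The list median was 0.05 (camera adjusted p = 0.148; without vehicle replicate 2, adjusted p = 0.0460). The chloride channel CFTR differed by 0.02 (SE 0.40), the calcium-activated chloride channel ANO1 by 0.65 (SE 0.21, adjusted p = 0.303) and the proton pump ATP12A by 1.2 (SE 0.59, adjusted p = 0.459). The 95% interval for CFTR ran from −0.90 to 0.94. The anion exchanger SLC26A4, pendrin, had 0.87 (SE 0.35, adjusted p = 0.379; with the replicate block 0.0377), and 2 members rose with the block.

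Detoxification and lipid mediator genes changed in single members. In the NRF2 and xenobiotic metabolism list GSTA1 and GSTA2 fell, 0 rose, and the median of 20 genes was −0.08 (camera adjusted p = 0.206; without vehicle replicate 3, adjusted p = 0.00647). Adjusted over the list alone, 1 rose and 2 fell. In the eicosanoid and fatty acid metabolism list ALOX15 was the 1 of 19 genes that rose, and 0 fell; 3 rose and 0 fell adjusted over the list alone, and the median was 0.10 (camera adjusted p = 0.173). HPGD, which inactivates prostaglandins, had 1.88 (SE 0.35, adjusted p = 0.0839; with the replicate block 0.0131), and the fatty acid elongase ELOVL5 had 0.83 (SE 0.14, adjusted p = 0.0557; with the replicate block 0.0265). With the replicate block 3 members of this list rose.

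Antimicrobial and mucosal defence genes had 1 call over all genes tested, and calls in both directions after adjustment over the list alone or with the replicate block. The endotoxin receptor TLR4 rose 3.60-fold (log2 fold change 1.85, SE 0.22, adjusted p = 0.0141) and was the 1 of 24 members that rose, with 0 that fell. TLR4 passed in 3 of the 6 fits that left out an array. Adjusted over the list alone, 2 rose and 2 fell. The median was −0.21 (camera adjusted p = 0.388; with the replicate block 0.034; with the replicate block and an estimated correlation, adjusted p = 0.421). S100A9, a calprotectin subunit, had −1.82 (SE 0.52, adjusted p = 0.258; with the replicate block 0.000579). S100A9 lay between 1.63 and 1.95 log2 units lower after IL-13 in the 3 numbered pairs. With the replicate block 2 members fell. The NF-kB cytokine and chemokine list had a median of −0.22 over 19 genes (camera adjusted p = 0.0314; adjusted p = 0.642 with an estimated correlation), and 0 rose or fell in limma, adjusted over all genes or adjusted over the list alone, against 0 and 1 at an unadjusted p under 0.05. CXCL8 had −0.92 (SE 0.47) and CXCL2 had −1.04 (SE 0.49). That shift missed the threshold without vehicle replicate 3 (camera adjusted p = 0.460), IL-13 replicate 1 (0.139) or IL-13 replicate 3 (0.0651). Interferon-stimulated genes had a median of −0.11 over 27 genes (camera adjusted p = 0.0522; with the replicate block 0.0226; with the replicate block and an estimated correlation, adjusted p = 0.421). This list also passed after quantile normalization (camera adjusted p = 0.0444), with array weights (0.00269) and without vehicle replicate 1 (0.00243), vehicle replicate 2 (0.0332) or IL-13 replicate 3 (0.00176). In limma 0 rose or fell over all genes tested, 1 rose and 2 fell adjusted over the list alone, and 1 and 3 were higher and lower at an unadjusted p under 0.05.

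Cell cycle genes had a median of −0.14 over 25 genes (camera adjusted p = 0.0104; adjusted p = 0.626 with an estimated correlation), and 0 rose or fell in limma, adjusted over all genes or adjusted over the list alone, against 0 and 6 at an unadjusted p under 0.05. The mitotic kinase BUB1 had −0.46 (SE 0.13, adjusted p = 0.236). The cell cycle shift missed the threshold without IL-13 replicate 1 (camera adjusted p = 0.105). The list's medians in numbered pairs 1, 2 and 3 were −0.06, −0.34 and 0.02. Hypoxia and glycolysis genes had a median of 0.02 over 21 genes (camera adjusted p = 0.668), and 0 rose or fell in limma, with 3 that rose and 2 that fell adjusted over the list alone and 4 and 2 higher and lower at an unadjusted p under 0.05. PFKP had 1.07 (adjusted p = 0.0632; with the replicate block 0.0167) and PFKFB3 had −0.74 (adjusted p = 0.152). The unfolded protein response and ER folding list had a median of −0.08 over 23 genes (camera adjusted p = 0.277).

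The other cell type lists gave little change in limma. Basal cell genes had a median of 0.01 and a mean of −0.01, the direction of the test, over 12 genes (camera adjusted p = 0.766), and KRT5 differed by 0.03 (SE 0.22). Squamous and cornified genes had a median of 0.03 over 18 genes (camera adjusted p = 0.680), ionocyte genes 0.11 over 10 (0.766), tuft cell genes 0.12 over 16 (0.660) and pulmonary neuroendocrine genes 0.15 over 8 (0.130; without vehicle replicate 1, adjusted p = 0.0124). Fibroblast and mesenchymal genes had a median of 0.03 over 13 genes (camera adjusted p = 0.430) and leukocyte genes 0.07 over 13 (0.554). Epithelial junction genes had a median of −0.06 over 18 genes (camera adjusted p = 0.259; without IL-13 replicate 3, adjusted p = 0.0308). Respiratory virus entry genes had a median of −0.04, the direction of the test, and a mean of 0.05 over 15 genes (camera adjusted p = 0.668). In these 9 lists and the ER folding list 0 genes rose or fell over all genes tested in limma, and each list had at most 1 gene higher and 3 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 neuroendocrine gene rose, 1 virus entry gene rose and 1 fell, and 0 passed in the others. The peptidase DPP4, a coronavirus receptor in the virus entry list, had 2.41 (SE 0.55, adjusted p = 0.165; with the replicate block 0.0354).

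The endothelial list had a median of 0.20 over 11 genes (camera adjusted p = 0.0104, and 0.626 with an estimated correlation). Of these genes 8 had a positive log2 fold change and 3 a negative one. The 3, PECAM1, TEK and EMCN, were named after their values were seen and differed by −0.09, −0.02 and −0.01. Their vehicle means of 3.61, 3.62 and 2.93 lay below the lower quartile of all clusters on each vehicle array. Whether the cultures held endothelial cells was not tested. The vascular endothelial growth factor receptor KDR was the 1 member that rose, by 1.24 on the log2 scale (SE 0.20, adjusted p = 0.0421), and 0 fell. KDR passed in 1 of the 6 fits that left out an array. Adjusted over the list alone, 2 rose and 0 fell. The shift missed the threshold without IL-13 replicate 2 (camera adjusted p = 0.151). The endothelial medians in numbered pairs 1, 2 and 3 were 0.11, 0.42 and −0.02. Across the 26 lists camera called 4 upward and 5 downward shifts. None of the 9 held with an estimated correlation, with which 2 lists had an unadjusted p under 0.05. Other divisions of the same 6 arrays into 3 and 3 gave up to 12 list calls with the preset correlation. These divisions held unequal numbers of IL-13 arrays on their sides, so they were not free of an IL-13 effect.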

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

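The divisions of the arrays into other groups and the pairings were tests chosen beforehand; the tests that weigh explanations for the lower ciliated cell genes, and the block without a replicate number, were chosen after the data were seen, while the list test itself and quantile normalization were planned.

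Signal appeared in clusters outside the gene comparison. Of the 11458 clusters that name several genes or none, 8 passed the threshold when every cluster was tested, 7 higher and 1 lower after IL-13. The 1709 clusters naming several genes gave 3 and 0 of these, and the 9749 naming none gave 4 and 1. Their largest log2 fold change was 1.91, and an unadjusted p under 0.05 was reached by 1041 of the 11458.

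The number of changed genes was larger for the labelled groups than for any other division of the arrays. The labelled division called 86 genes, and the other 9 of the 10 possible divisions into 3 and 3 called 0 each with limma, with 176 to 1386 genes at an unadjusted p under 0.05 against 2187 for the labelled groups. So 1 of 10 divisions gave as many, and 10 divisions are too few for a share under 0.05. Each other division mixed IL-13 and vehicle arrays on both sides, in unequal numbers. Part of any IL-13 effect stayed in the difference and part entered the error, so these divisions do not stand for arrays without an effect. For lists the labelled groups gave 9 calls, and 3 of 10 divisions gave as many, again too few for a share under 0.05. The others were vehicle 1, vehicle 2 and IL-13 1 against the rest, with 12, and vehicle 1, IL-13 1 and IL-13 2 against the rest, with 11. Among the 4 divisions that part all 3 numbered pairs, the other 3 called 0 genes and 4 to 8 lists.

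With the replicate number as a block, calls went from 86 to 172, 113 higher and 59 lower. Without replicate 1, 2 or 3 the block called 224, 145 and 1383. Those fits held fewer arrays, and the block left little from which to estimate each gene's own error. That error then leaned more on the values of all genes, so 1383 calls are not stronger evidence than 172. Of the 6 ways to pair the IL-13 arrays with the vehicle arrays, the labelled pairing called the most genes, so that 1 of 6 gave as many, and the highest other pairing called 123. With 6 pairings a share under 0.05 cannot be reached. The extra calls may reflect something that same-numbered samples share, as their deviations would allow, or a chance match of replicate numbers. These cannot be told apart because the pairings are so few. What samples of the same number share, a donor or anything else, is not given by the labels.

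Ciliated cell axoneme genes had a median log2 fold change of −0.28, and 29 of 31 members were negative. Array scaling as the whole cause is argued against by a shift relative to all genes of −0.262 after quantile normalization (−0.290 as deposited). Against 1 culture pair alone stand numbered pair medians of −0.243, −0.361 and −0.321, but the labels do not say that the numbers mark pairs. The list's level, a median of values centred per gene, was 0.242, 0.182 and 0.022 on vehicle arrays 1, 2 and 3. On IL-13 arrays 1, 2 and 3 it was −0.008, −0.155 and −0.231, so vehicle 3 and IL-13 1 lay close together. How even the shift was across cultures therefore depends on which arrays are matched. A lower share of ciliated cells, with all their genes falling alike, cannot be told apart from a change within the cells: the regulators lay further down (permutation p = 0.00294 across genes, which are not independent, two-sided, 100000 permutations), but in 2 of the 3 pairs. Differences between single cultures that do not follow IL-13 stay open because the divisions are too few for a share under 0.05: of the 4 that part all numbered pairs, 1, the labelled one, gave a median shift as large (0.281 in size, highest other 0.153), and of all 10, 2 did, the other (vehicle 1, vehicle 2 and IL-13 1 against the rest, 0.306) parting 1 pair. A response of ciliated cells to IL-13 remains a hypothesis.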

How the results depend on the processing

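The combination of the replicate block with an estimated correlation or with omission of a replicate number was chosen after the data were seen; every other alternative was chosen beforehand. Quantile normalization, median centring, a floor at the 20th percentile and averaging of clusters kept the counts within 66 to 78 higher, 16 to 23 lower and 9 or 10 lists. With the replicate block 113 genes were higher and 59 lower, and 0 of the 86 calls ended. In this balanced design the block leaves each log2 fold change unchanged, so no sign could change. Apart from the genes and lists given with their blocked values, the block changed no other call among the lists and their members. The block without replicate 1 gave 131 and 93, without replicate 2 it gave 105 and 40, and without replicate 3 it gave 741 and 642. Of the 86 calls, 74, 66 and 86 were shared. Those fits left little from which to estimate each gene's own error, so their larger counts are not stronger evidence. Array weights gave 367 and 330, with a weight of 5.02 for IL-13 replicate 1 and 0.416 for IL-13 replicate 3. An intensity trend with a robust prior gave 33 lower, and a minimum 2-fold change gave 8 lower. Testing every cluster gave 28 higher and 2 lower, where 30441 tests were adjusted for. Leaving out 1 array gave 21 to 47 higher and 1 to 16 lower, where fewer samples were fitted: without vehicle replicate 1, 2 and 3 it was 21 and 1, 24 and 2, and 40 and 9, and without IL-13 replicate 1, 2 and 3 it was 26 and 1, 30 and 3, and 47 and 16. The sign of the 86 genes could not change in those 6 fits, because their groups did not overlap. Of the 86 calls, 18 were kept in each fit. CCL26 ranged from 3.80 to 5.10 in log2 fold change over those 6 fits, with an adjusted limma p of up to 0.115. Without the 40% dimmest genes, multiciliogenesis regulators (camera adjusted p = 0.0599), club and secretory (0.0599), NF-kB (0.149) and cell cycle (0.263) lost the call. The regulators had then lost CDC20B and DEUP1. Lists past the threshold numbered 5 in that fit. They numbered 0 with an estimated correlation, 0 with the replicate block and an estimated correlation (smallest adjusted p 0.0763 and 0.179; 2 and 1 lists at an unadjusted p under 0.05), 2 with fry for 1 direction (the type 2 signature and the multiciliogenesis regulators; goblet and mucous had an adjusted p of 0.111) and 12 with fry for either direction. The latter added the JAK-STAT, NRF2, antimicrobial, eicosanoid and hypoxia lists and lost NF-kB (0.553) and cell cycle (0.131). O-glycosylation lost the call with array weights (adjusted p = 0.0593). Leaving out 1 array gave 6 to 11 lists. Except where the construction is named, the cause was not tested. Among the 130 genes named by the rule, alternatives gave 1743 results on the same side of the threshold, 113 no longer past it and 68 newly past it. No call took the opposite sign; 13 results for uncalled genes or lists changed sign. Signal over background was not measured here, so genes at the lowest percentiles limit what a fold change can show.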

Other observations

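All genes in this part were singled out after their values were seen unless they belong to the lists, and the test of gene families was chosen after the result was seen.

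Of the 69 genes that rose, 7 were solute carriers, a number that did not pass a test for excess (adjusted p = 0.112). The monocarboxylate transporter family member SLC16A9 rose 5.26-fold (log2 fold change 2.39, SE 0.36, adjusted p = 0.0354), the sodium-coupled monocarboxylate transporter SLC5A8 rose by 1.37, the zinc and manganese importer SLC39A8 by 1.12, SLC24A3 by 1.04, SLC45A4 by 0.99 and the copper importer SLC31A1 by 0.93; the other was SLC12A2. Of the 6 fits that left out an array, SLC5A8 passed the threshold in 6, SLC12A2 in 2, and each of the other 5 solute carriers in 1. Single genes outside the lists also rose. SERPINB4, a serpin of squamous epithelia, rose 6.99-fold to 9.76 ± 0.45 (SD, n = 3), the membrane mucin MUC21 rose 4.73-fold, the neutral endopeptidase MME 3.33-fold, the tetraspanin TSPAN8 2.93-fold, the connexin GJB1 2.66-fold and the neurokinin receptor TACR1 2.58-fold. CD274, the checkpoint ligand PD-L1, rose by 1.11 on the log2 scale (SE 0.17, adjusted p = 0.0424), and the cysteine protease CTSC rose by 1.18 (adjusted p = 0.0467). The connexin GJB7 fell while GJB1 rose. Among transcription factors RUNX2 rose by 0.70 and ETS1 fell by 0.73. Of the 6 fits that left out an array, MME passed in 6, SERPINB4 in 5, GJB1 in 4, MUC21 in 2, and TSPAN8, TACR1, GJB7 and ETS1 in 1 each, while CD274, CTSC and RUNX2 passed in 0 (highest adjusted p 0.181, 0.214 and 0.227).

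Some genes passed the threshold with the replicate block and not without it. S100A8 had a log2 fold change of −1.59 (SE 0.67, adjusted p = 0.398; with the replicate block 0.00234), the complement proteases C1R −0.94 and C1S −1.18 (with the replicate block 0.0377 and 0.0327), and the class II antigen gene HLA-DPB1 −1.02 (with the replicate block 0.0171). KLF4 had 1.17 (with the replicate block 0.00509), CD44 1.18 (0.00958) and CSTA 1.03 (0.0383). Without the block the adjusted limma p-values of these genes lay between 0.177 and 0.398.

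A hypothesis that solute carriers were over-represented among the increases was tested with a one-sided Fisher's exact test over families of genes sharing a symbol stem. The 7 solute carriers compared with 1.43 expected from 372 tested, an adjusted p of 0.112 over 480 tests of 240 families and both directions. The CEACAM (CEACAM5 and CEACAM21), SERPINB (SERPINB4 and SERPINB10) and CST (CST1 and CST2) families had the same adjusted p of 0.112, each with 2 members that rose of 11, 11 and 12 tested, against 0.0422, 0.0422 and 0.0460 expected. None of the 240 families passed the threshold after adjustment, so each excess may be chance.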
